A study of Mus musculus with 3 samples.

How the data were processed

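Gene expression was measured in single cells from liver nonparenchymal preparations of male C57BL/6J mice, in 1 library per group: saline control, poly(I:C) for 7 h followed by LPS for 3 h, and poly(I:C) for 7 h followed by LPS for 12 h. Per the labels' protocols, livers were perfused with collagenase, minced and filtered, hepatocytes were removed by low-speed spins, and droplet libraries were converted for sequencing on an MGISEQ-2000 instrument. The deposited values are UMI counts per gene and barcode, not normalised, and per the submitters' processing notes they were made with Cell Ranger (version not given in the sources used here), with FastQC 0.11.7 and the genome build mm9. Barcodes with fewer than 500 UMIs do not occur in either matrix. Gene names and identifiers were taken from the feature list of 31053 genes that came with the counts. Because the genome build behind that list was not settled, no coordinates are given. The expression values of the 12 h library were not analysed here, and only its barcodes were counted.

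Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from the 13 mitochondrial genes, which left 11655 control and 14104 LPS barcodes. Doublets were scored in each library as the share of simulated doublets (sums of random pairs of its barcodes) among the nearest neighbours of a barcode. The highest scores were called up to 0.8% per 1000 barcodes, an expected rate of 9.67% in the control and 11.6% in the LPS library. With ties left uncalled, 1081 control (8.95%) and 1575 LPS barcodes (10.8%) were called, and 10575 and 12532 barcodes were kept after both steps.

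Both libraries were clustered together on 2000 variable genes, 30 principal components and a shared-neighbour graph of 20 neighbours, with the Leiden method at resolution 1, which gave 29 clusters. Left out of this step were 2533 genes: the members of the response lists and other genes over 4-fold apart between the summed libraries. Clusters were named from 18 marker sets, as "like" classes. A marker counted as detected in a cluster at 20 CPM or more and at least 25% of the level in the highest cluster, and a name needed at least 3 detected markers. Each cluster could take only the class with its highest score, the mean marker level relative to the highest cluster. The markers were chosen before the data were examined, as were the gene lists, filters, rule for named genes and most alternatives. The rule that turns markers into names was written after the clusters had been seen and then revised 2 times. As first written, it took leading genes against all other cells of a library and left 4 clusters unnamed: cluster 1 (41.2% of the control and 0.0319% of the LPS library), cluster 3 (0.199% and 20.7%) and cluster 28 (0% and 0.471%), later T cell-like, and cluster 22 (0.738% and 0.670%), later monocyte-like. The first revision took leading genes against cells of other classes, because T cells made up most of a library, and the second took marker levels against the highest cluster of either library. Most clusters came from 1 library, so a cluster may stand for a library and not for a cell type.

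Within each class, counts were summed per library and divided by the class total (CPM), and log2 ratios of the LPS over the control library were taken with 0.5 added to each count. Folds are ratios of CPM with exact 95% intervals. A fold against a count of 0 was computed against a floor of 3 counts in the class and is a lower bound. T cell-like, NK/ILC1-like and B cell-like cells, the 3 classes with at least 100 kept cells in both libraries, were compared. Hepatocyte-like barcodes of the control were too few. Genes were named by rule: per class, the 12 highest and 8 lowest log2 ratios among genes with at least 50 UMIs and 50 CPM in the library where they were higher, leaving out hepatocyte, erythroid and mitochondrial genes and genes under 10% of the level in the highest class. Up to 4 members of each list with the largest ratios, markers of a class, cytokine genes and the LPS receptors could be named too. After the data were seen, list members at least 2-fold apart were also counted by whether they lay under 10% of the level in the highest class, in the library where they were higher, since such levels can come from free RNA.

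The 25 gene lists covered type I interferon response, interferon-gamma targets, inflammatory cytokines, chemokines, NF-kB feedback and targets, endothelial adhesion and coagulation, LSEC identity, Kupffer cell identity, MHC class II, MHC class I and immunoproteasome, inflammasome and lytic death, LPS and double-stranded RNA sensing, cytotoxic effectors, acute phase, glycolysis, metallothionein and oxidative stress, immediate early and dissociation stress, cell cycle, neutrophil maturation and trafficking, stellate activation, complement, anti-inflammatory regulators, lymphocyte activation, cytosolic ribosomal proteins and the nuclear-encoded respiratory chain. Of 465 list entries, 7 had no match among the gene names. A member was measured with at least 20 UMIs in both libraries together. Each list is described by its members at least 2-fold apart, its median log2 ratio and the percentile of that median among 10000 random lists of equal size drawn from the same 20 expression bins. Percentiles describe these libraries and are no test across mice.

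The ratio step was tested on simulated counts drawn from the real means and class totals, with 200 genes changed. Only genes with at least 200 control UMIs in the class were simulated, with Poisson noise, which the intervals also assume. In T cell-like cells (9022 genes) true folds of 2 and 4 came out at medians of 2.03 and 4.00001, in NK/ILC1-like cells (5839 genes) at 1.99 and 3.98, and in B cell-like cells (1645 genes) at 1.98 and 3.995. The 95% intervals held the true fold of 2 for 92%, 88% and 98% of its genes in the 3 classes, and 0% of unchanged genes came out 2-fold apart. These figures check the arithmetic and do not cover genes with fewer UMIs or spread beyond counting error.

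Alternatives were a stricter barcode filter (1000 UMIs, 500 genes, 10% mitochondrial), no filter, doublets kept, each library clustered on its own, response genes kept in clustering, resolution 2, TMM scaling (trims of 30% and 5%), a total without hepatocyte, erythroid, mitochondrial and ribosomal genes (the reduced total), the mean of each cell's CPM, 3 added to each count, and list minimums of 1 and 100 UMIs. Added after the data were seen were shares without hepatocyte-like barcodes, every pair of a control and an LPS cluster of a class with at least 50 cells each, T cell-like cells without the cycling cluster, the naming rule first written, and ratios of some NK/ILC1-like genes between the pair of clusters with Eomes and the pair without. With no replicate spread, a share or gene ratio counted as moved when it left its 95% interval, a list median when it moved by over 0.5, and a count when it differed by over 1.5 times. Which list counts are printed was widened to lists with at least 5 genes on 1 side after a look at the alternatives. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.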

Results

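Single-cell RNA sequencing profiled nonparenchymal liver cells of male C57BL/6J mice in a model of endotoxemia. Poly(I:C), a synthetic double-stranded RNA that mimics viral RNA, was given to prime the animals, and lipopolysaccharide (LPS), a cell wall component of Gram-negative bacteria, was given 7 h later. The series holds 3 groups with 1 library each: saline control, LPS for 3 h and LPS for 12 h. Its design text gives 6 mice aged 8 weeks per group and leaves open how they were combined. The expression values of the 12 h library and a group given poly(I:C) alone, which the labels describe, were not analysed here. The comparison therefore asks how liver nonparenchymal cells 3 h after LPS in primed mice differed from those of saline-treated mice, and the contributions of poly(I:C) and LPS are not separated. With 1 library per group, no difference has a replicate check and no test was run. All 95% intervals, exact Poisson for counts and Clopper-Pearson for shares, cover counting error only.

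The control library held 12084 barcodes with 71286695 unique molecular identifiers (UMIs), and the 3 h library, called the LPS library from here on, held 14542 barcodes with 53624889 UMIs. Median depth was 4727 UMIs and 1908 genes per barcode in the control library and 3262 UMIs and 1327 genes in the LPS library. The lower quartile was 3812 UMIs in the control and 1072 UMIs in the LPS library. The lowest total in both libraries was 500 UMIs. After the barcode filter and the removal of called doublets, 10575 control and 12532 LPS barcodes were kept.

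Lymphocytes made up most of both libraries, and the LPS library held more hepatocyte-like and fewer endothelial-like barcodes. Hepatocyte-like barcodes were 0.199% of the control library (21 barcodes, 95% interval 0.123 to 0.303%) and 27.3% of the LPS library (3415 barcodes, 26.5 to 28.04%). Liver sinusoidal endothelial cell (LSEC)-like cells, the lining of the liver's fenestrated capillaries, were 2.44% (258 cells, 2.15 to 2.75%) in the control and 0.0160% (2 cells, 0.00193 to 0.0576%) in the LPS library, or 2.93% and 0.262% with doublets kept. Plasmacytoid dendritic-like cells, known for their output of type I interferon, were 0.823% of control cells (87 cells, 0.659 to 1.01%) and 0 of 12532 LPS cells, which allows a share of up to 0.0239% by the floor of 3 counts, or 0.0294% by the upper Clopper-Pearson limit. Erythroid-like barcodes were 1.92% (1.67 to 2.1995%) and 0.231% (0.155 to 0.332%). Under the alternatives, shares were taken only for T cell-like, NK/ILC1-like, B cell-like, hepatocyte-like and LSEC-like barcodes. Low or zero shares of other classes were therefore not checked with doublets kept or without a filter.

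The hepatocyte-like barcodes of the LPS library were shallow, with a median of 696 UMIs and 14.3% mitochondrial UMIs, and lay in clusters 2, 12 and 27. A stricter barcode filter of at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs left their share at 0.553% in the LPS and 0.0999% in the control library. The submitters' protocol removed hepatocytes with a low-speed spin, and their design text names the LPS material parenchymal where the labels say nonparenchymal. Hepatocyte genes in lymphocytes did not follow this share: the hepatocyte markers summed to 111 CPM (UMIs scaled to a common class total) in T cell-like cells of the control and 58.1 CPM in those of the LPS library.

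T cell-like cells were 68.03% of the control library (7194 cells, 67.1 to 68.9%) and 47.5% of the LPS library (5954 cells, 46.6 to 48.4%). Under the naming rule first written, which left clusters 1, 3 and 28 of this class unnamed, the shares were 26.7% and 26.3%. Natural killer cell and type 1 innate lymphoid cell (NK/ILC1)-like cells held 15.1% (1596 cells, 14.4 to 15.8%) and 14.7% (1843 cells, 14.1 to 15.3%). B cell-like cells held 7.102% (751 cells, 6.62 to 7.61%) and 8.83% (1107 cells, 8.34 to 9.34%). With the hepatocyte-like barcodes left out of the denominator, a comparison added after the data were seen, the control and LPS shares were 68.2% and 65.3% for T cell-like, 15.1% and 20.2% for NK/ILC1-like, and 7.12% and 12.1% for B cell-like cells, so the NK/ILC1-like share turned from lower to higher. Median depth in the control and LPS libraries was 4849.5 and 4098 UMIs for T cell-like, 4304 and 3564 UMIs for NK/ILC1-like, and 2748 and 2450 UMIs for B cell-like cells.

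The smaller classes were each held by 1 cluster. Plasma cell-like barcodes were 2.32% of the control and 0.0638% of the LPS library, at a median of 982 UMIs and 9.79% mitochondrial UMIs in the control. Monocyte-like cells (cluster 22, unnamed under the first naming rule) were 0.738% (0.583 to 0.920%) and 0.670% (0.535 to 0.829%). Those of the control held 95.8% of the Il12b and 85.6% of the Ccl22 UMIs of that library, genes of activated dendritic cells, so these shares are not shown to be of 1 cell type. Neutrophil-like cells were 0.662% (0.516 to 0.836%) and 0.391% (0.289 to 0.517%), and cluster 25 held 0.482% and 0.327%. Cluster 25 carried the basophil genes Prss34 and Mcpt8 but was also led by Mpo, Prtn3, Elane and Ctsg, granule genes of immature neutrophils, and is given by number. Mesothelial-like cells numbered 21 in the control (0.199%) and 0 in the LPS library. No cluster scored highest for Kupffer cell, stellate cell, cholangiocyte or conventional dendritic cell markers, so none was named so. These markers were not all missing: the stellate set scored second in the mesothelial-like cluster 29 (0.45). The conventional dendritic set scored second in the plasmacytoid dendritic-like cluster 26 (0.44).

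**Figure D1:**
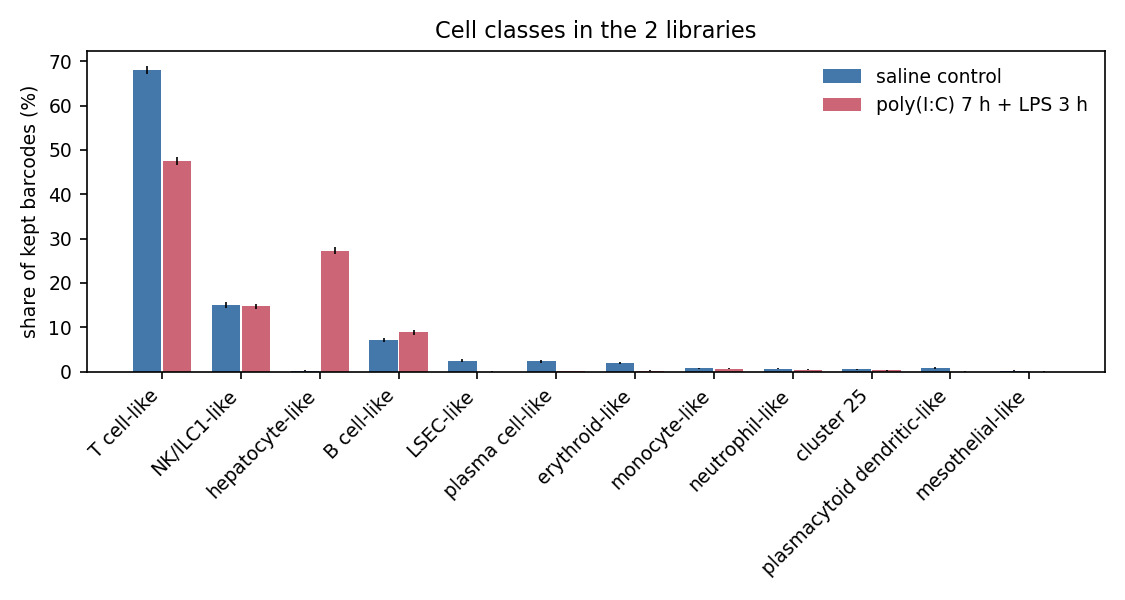
Share of kept barcodes (percent, axis from 0) held by each cell class in the control and LPS libraries, with exact 95% Clopper-Pearson intervals as error bars, 1 library per group. Hepatocyte-like barcodes stand at 0.199% in the control and 27.3% in the LPS library, and LSEC-like cells at 2.44% and 0.0160%, or 2.93% and 0.262% with doublets kept.

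Summed over all kept barcodes, the LPS library differed from the control in hepatocyte, endothelial and interferon-induced genes. Hepatocyte genes led the higher side. Cyp4a14, a fatty acid omega-hydroxylase under PPAR-alpha control, stood at 0.510 CPM in the control and 235 CPM in the LPS library, 462-fold higher (323 to 684). Mup20, a major urinary protein that shares sequence with its family, was 255-fold higher (234 to 278), and Cyp4a10 (165-fold, 119.7 to 235), the apolipoprotein gene Apon (94.8-fold, 67.7 to 137), the amino acid transporter Slc38a4 (68.4-fold, 52.1 to 91.6) and the fatty acid transporter Slc27a2 (63.8-fold, 50.1 to 82.5) followed. The interferon-induced genes Trim30c (153-fold, 108 to 224), Cxcl10 (97.04-fold, 93.2 to 101), Oas2 (91.04-fold, 75.5 to 111), Usp18 (64.996-fold, 58.4 to 72.5) and Ifi211 (68.03-fold, 57.8 to 80.6) and the acute phase gene Saa3 (62.5-fold, 55.4 to 70.8) were the others.

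Endothelial genes led the lower side of the whole-library comparison. Ptprb, a vascular phosphatase, stood at 79.3 CPM in the control and 0.167 CPM in the LPS library, 475-fold lower (230.2 to 1181). The LSEC lectin Clec4g (449-fold, 206 to 1226), the water channel Aqp1 (249.7-fold, 154 to 437), the nuclease Dnase1l3 (113-fold, 74.9 to 178), Igfbp7 (84.6-fold, 63.5 to 115) and Timp3 (65.8-fold, 46.8 to 95.8) were lower too, as was Dcn (40.3-fold, 31.8 to 52.1), a proteoglycan of stromal and mesothelial cells. Of the LSEC identity list, 18 of 20 measured genes were at least 2-fold lower, with a median log2 ratio of -6.62, or -5.70 with genes at 0 set at their bound. Of the endothelial adhesion and coagulation list, 13 of 22 were lower and 4 higher. The acute phase list, made of genes that hepatocytes express, had 17 of 18 measured genes at least 2-fold higher and a median log2 ratio of 4.07. LSEC-like cells were 2.44% of control and 0.0160% of LPS barcodes, or 2.93% and 0.262% with doublets kept, and hepatocyte-like barcodes 0.199% and 27.3%. Ratios over all kept barcodes were not taken under the alternatives. The size of the endothelial folds may therefore depend on doublet removal, which their intervals do not cover.

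T cell-like cells of the LPS library differed from control T cell-like cells most in interferon-induced genes. All 29 measured genes of the type I interferon response list were at least 2-fold higher, with a median log2 ratio of 4.75, at the 100 percentile of 10000 random lists of equal size and similar expression. Of these 29 genes, 1 was under 10% of the level in the highest class. Interferon-gamma targets (17 of 18 at least 2-fold higher, median 3.06), antigen presentation by major histocompatibility complex (MHC) class I (10 of 16, median 1.26) and lymphocyte activation genes (7 of 14, 3 of them under 10% of the level in the highest class, with 2 lower, median 1.03) also stood higher, each at the 100 percentile. T cell-like cells came from clusters 1, 9, 11, 13, 15 and 17 in the control and 3, 4, 8, 17, 18, 24 and 28 in the LPS library, and the cycling cluster 17 alone held more than 50 cells of each library. Over the 42 pairs of a control and an LPS cluster, 7 of 25 lists kept their sign: the 4 just given and the cytokine, NF-kB and stellate activation lists.

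The antiviral gene Rsad2 (viperin) stood at 7.67 CPM in the control and 733 CPM in the LPS library, 95.5-fold higher (85.5 to 107). Cxcl10 (ENSMUSG00000034855), which encodes the ligand of the chemokine receptor Cxcr3, stood at 39.4 and 3725 CPM, 94.6-fold higher (90.1 to 99.5). The oligoadenylate synthetase gene Oas2 (ENSMUSG00000032690) was 108-fold higher (86.4 to 138), Usp18, which encodes a protease that removes ISG15 and limits interferon receptor signalling, 68.2-fold (59.9 to 77.9), and the antiviral GTPase gene Mx1 54.99-fold (49.95 to 60.7). Oasl2 (75.4-fold, 65.97 to 86.5), Ifit3 (65.1-fold, 60.2 to 70.4), Ifit3b (71.7-fold, 60.6 to 85.4), the Schlafen gene Slfn5 (60.8-fold, 57.7 to 64.02) and the mitochondrial nucleotide kinase gene Cmpk2 (60.5-fold, 53.6 to 68.5) were higher as well. Among genes that passed the rule for named genes, the largest ratios were those of Trim30c (ENSMUSG00000078616, 154-fold, 105 to 237) and the DNA sensor gene Ifi204 (144-fold, 119.8 to 175). Under the first naming rule these were 98.5-fold and 73.6-fold higher, and Cmpk2 37.9-fold. Trim30c, Ifi204, Ifit3 and Ifit3b have near-identical family members, as do the Oas, Tgtp, H2, Saa, Mup, Phf11 and Klra genes and Ifi211, and how shared reads were assigned is not given in the sources used here, so their single values are uncertain.

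The T cell-like cells of the LPS library also had higher Gzmb (ENSMUSG00000015437), which encodes granzyme B (181 against 1777 CPM, 9.84-fold higher, 9.604 to 10.1). Of the cytotoxic effectors list, 4 of 13 genes were at least 2-fold higher and 0 lower, with a median of -0.16, or 0.21 under TMM scaling and -2.80 to 5.09 over the pairs of clusters. Besides Gzmb these were Tnfsf10, which encodes the death ligand TRAIL (2.75-fold, 2.604 to 2.91), Serpinb9 (2.53-fold, 2.397 to 2.67) and Gzma, at 2.34-fold in the main comparison against 1.16-fold with the stricter filter and 1.17-fold with separate clustering. Gzma was under 10% of the level in the highest class. Among activation genes, Cd69, an early activation marker that holds lymphocytes in tissue, was 3.899-fold higher (3.803 to 3.997), Myc 6.17-fold (5.82 to 6.54) and the costimulatory ligand Cd86 15.3-fold (12.9 to 18.2). The checkpoint ligand Cd274 (PD-L1) stood at 31.7 and 250.1 CPM, 7.89-fold higher (7.43 to 8.37). In the class I list, the peptide-loading gene Tapbp was 4.46-fold (4.36 to 4.57) and the immunoproteasome gene Psmb10 4.25-fold (4.14 to 4.36) higher. The interferon-gamma target genes Iigp1 (34.9-fold, 31.9 to 38.3) and Gbp2 (24.9-fold, 23.8 to 26.1) encode GTPases that attack vacuoles of intracellular pathogens.

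Single genes of lytic death and of nucleic acid sensing were higher in the T cell-like cells of the LPS library. Of those named below, Zbp1, Ifih1 and Ddx58 are also members of the type I interferon response list and were already counted there. Of the inflammasome and lytic death list, 5 of 17 were at least 2-fold higher and 1 lower, or 9 higher and 0 lower under TMM scaling (median 0.78, or -0.69 in the lowest pair of clusters), among them Zbp1, a sensor of Z-form nucleic acids (10.8-fold, 10.4 to 11.3), its downstream necroptosis effector Mlkl (28.9-fold, 21.8 to 39.1), Casp4, the mouse caspase-11 that binds intracellular LPS (4.803-fold, 4.28 to 5.404), and Casp8 (3.16-fold, 3.05 to 3.28), with Casp4 under 10% of the level in the highest class. The LPS and dsRNA sensing list had 7 of 17 genes higher and 2 lower, with a median of 0.02, or -0.02 under the stricter filter and -0.33 in the lowest pair of clusters. The largest ratios were those of 4 genes that respond to double-stranded RNA, Tlr3 (38.5-fold, 19.9 to 85.3), Ifih1 (22.2-fold, 20.4 to 24.2), Ddx58 (7.22-fold, 6.92 to 7.53) and Eif2ak2 (12.5-fold, 11.7 to 13.4), and the other higher members were Myd88 and, under 10% of the level in the highest class, Tlr2 and, on 10 and 20 UMIs, Cd14, with a log2 ratio of 1.53, or 0.93 under the first naming rule. Cytokine genes (9 of 15 higher, or 5 under the first naming rule and 5 over genes with at least 100 UMIs, 0 lower, median 1.46) were under 10% of the level in the highest class for 6 of the 9, and the other 3 included Lif (37.4-fold, 27.2 to 52.6). The NF-kB feedback and targets list had 12 of 26 genes higher (4 of them under that level), 0 lower and a median of 0.77, with the feedback inhibitor Socs3 at 3.07-fold higher (2.94 to 3.204). Of the chemokine list, 6 of 15 were higher and 2 lower, but all of them except Cxcl10 were under 10% of the level in the highest class and are not read as T cell expression, such as Cxcl2 at 3.64 CPM against 3408 CPM in neutrophil-like cells. The list had a median of 0.03, or -0.34 under the stricter filter and -1.78 in the lowest pair of clusters.

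On the lower side, the ratios furthest from 1 by the naming rule were those of Sytl2, Rflnb and Itga1. Cxcr3 itself stood at 138 CPM in the control and 9.78 CPM in the LPS library, 14.1-fold lower (12.5 to 16.0002). The collagen-binding integrin gene Itga1, a marker of tissue-resident lymphocytes, was 17.1-fold lower (14.7 to 19.95), and 33.6-fold lower with separate clustering. Sytl2, which encodes a vesicle-docking protein, was 22.6-fold lower (18.5 to 27.9), followed by the actin regulator gene Rflnb (20.1-fold, 16.5 to 24.8), Mxd4, whose product opposes Myc (14.3-fold, 12.7 to 16.2), the myosin gene Myo1f (14.3-fold, 12.2 to 16.8), Ubash3b, which encodes a phosphatase that dampens T cell receptor signalling (12.01-fold, 9.99 to 14.6), and Prrt1 (11.8-fold, 9.996 to 14.1). Among the marker genes, Cd3e was 2.08-fold (2.01 to 2.14), Trac 2.41-fold (2.35 to 2.48) and Cd4 2.16-fold (2.004 to 2.33) lower, while Cd8a was 1.497-fold higher (1.43 to 1.56). Il7r had a log2 ratio of 0.24, or -0.11 under the first naming rule. The largest cluster with Cd4 detected made up 60.5% of the class in the control (cluster 1) and 43.5% in the LPS library (cluster 3). The largest with Cd8a made up 12.0% (cluster 9) and 33.0% (cluster 4). Ratios of single genes were not taken between these clusters, so a different make-up of the class may contribute to the ratios. Of the cell cycle list, 12 of 16 genes were at least 2-fold lower (median -1.72), led by Ube2c (7.33-fold, 6.49 to 8.301, or 3.76-fold with doublets kept) and Ccna2 (6.27-fold, 5.13 to 7.72, or 3.41-fold). Cycling cells of cluster 17 numbered 267 in the control and 55 in the LPS library, and without that cluster 5 genes were lower, 1 was higher and the median was -0.59.

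The median log2 ratio of all genes in T cell-like cells was -0.43, and TMM scaling, which assumes that most genes are unchanged, moved it to -0.06. In NK/ILC1-like cells it was -0.38 and moved to -0.05, and in B cell-like cells it was -0.29 and moved to 0.02. The ratios given here are relative to total UMIs and lie lower than TMM-scaled ratios by these shifts.

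NK/ILC1-like cells of the LPS library had higher interferon response, cytokine and activation genes, and some cytotoxic genes were higher too. All 29 measured type I interferon response genes were at least 2-fold higher (median 4.71, 100 percentile), 3 of them under 10% of the level in the highest class. Of the interferon-gamma targets, 15 of 18 were higher and 1 lower (median 2.61). Gzmb stood at 1096 CPM in the control and 12448 CPM in the LPS library, 11.4-fold higher (11.1 to 11.6). Ifng (ENSMUSG00000055170), the gene of interferon-gamma, stood at 251 and 1170.3 CPM, 4.67-fold higher (4.46 to 4.89), and the perforin gene Prf1 was 4.22-fold higher (4.05 to 4.396). These cells came from clusters 7 and 14 in the control and 5 and 16 in the LPS library, of which 14 and 5 carried Eomes and Klra8, as NK cells do, and 7 and 16 did not. The clusters with Eomes made up 32.8% of the class in the control (cluster 14) and 74.3% in the LPS library (cluster 5), and Eomes itself was 2.58-fold higher in the class (2.38 to 2.79). Ratios were therefore also taken between the clusters with Eomes and between those without, in that order. Gzmb was 23.2-fold (21.9 to 24.5) and 8.68-fold (8.46 to 8.8997) higher, Ifng 6.09-fold (5.55 to 6.69) and 2.36-fold (2.19 to 2.55), and Prf1 2.2006-fold (2.09 to 2.32) and 1.39-fold (1.25 to 1.55).

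Of the cytotoxic effectors list, 5 of 13 genes were at least 2-fold higher and 0 lower in NK/ILC1-like cells (median 0.56), though between cluster 14 and cluster 16 the median was -0.31. Gzma was 2.32-fold (2.299 to 2.34) and Serpinb9, whose product shields cells from granzyme B, 3.33-fold (3.17 to 3.496) higher, the latter 1.94-fold (1.76 to 2.13) between the clusters without Eomes. Lymphocyte activation genes were higher (8 of 13, 2 lower, median 2.03): Tnfrsf9 (4-1BB) at 55.3 against 656 CPM, 11.9-fold higher, 10.8 to 13.02 (5.38-fold between the clusters without Eomes), and the high-affinity IL-2 receptor gene Il2ra at 6.11-fold (5.25 to 7.13), or 12.7-fold with the stricter filter and 30.7-fold between the clusters with Eomes. Cytokine genes (8 of 11 higher, or 5 over genes with at least 100 UMIs, 0 lower, median 2.23) held Il6 and Il1b, both under 10% of the level in the highest class of the LPS library, with Il6 at 3.502 CPM against 203 CPM in cluster 25. The other 6 included Il15 (9.72-fold, 7.35 to 13.1), Lif (16.8-fold, 9.76 to 31.3) and Il10, which had 2 UMIs in the control and 40 in the LPS library (24.9-fold, 6.45 to 212, or 10.1-fold with doublets kept and 10.7-fold with 3 added to each count). The median of the cytokine list is the log2 ratio of Il1b, which was 0.24 under the stricter filter and 0.72 with separate clustering. Chemokine genes (6 of 9 higher, 0 lower, median 1.37), of which Ccl2, Cxcl2 and Ccl9 were under 10% of the highest class, included Ccl4 (2184 against 5872 CPM, 2.69-fold higher, 2.64 to 2.73).

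Cxcl10 had the largest ratio in NK/ILC1-like cells (24.9 against 5487 CPM, 220.2-fold higher, 193 to 252). Interferon-induced genes followed: Ifi204 (179.9-fold, 133 to 249), Ifi211 (178-fold, 112 to 301), Ifi44 (112-fold, 56.6 to 261), Usp18 (82.9-fold, 62.02 to 114), Mx1 (74.9-fold, 58.9 to 96.6), Phf11a (75.2-fold, 47.9 to 125), Oasl2 (65.2-fold, 43.6 to 102), Slfn5 (54.1-fold, 46.5 to 63.2) and Oasl1 (47.5-fold, 36.4 to 63.3). The other higher genes by the naming rule were the proteoglycan gene Sdc3 (86.4-fold, 43.5 to 201) and P2ry14, which encodes a receptor of UDP-glucose (77.003-fold, 48.5 to 130.4). The NF-kB feedback and targets list was higher in 13 of 23 genes and lower in 0 (median 1.10), among them Bcl3 (9.88-fold, 8.43 to 11.6) and the adhesion gene Icam1 (4.85-fold, 4.57 to 5.15). The MHC class I list had 8 of 16 genes higher and 0 lower (median 0.96). The inflammasome and lytic death list had 6 of 15 higher and 2 lower (median 0.67), among the higher Casp4 at 20.4 and 279.9 CPM (13.7-fold, 11.8 to 16.04) and Zbp1 (12.96-fold, 11.8 to 14.3).

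On the lower side, Dtx1, a Notch pathway gene, stood at 61.1 CPM in the control and 1.21 CPM in the LPS library, 50.4-fold lower (26.4 to 111), with 31.3-fold under the stricter filter, 24.03-fold with doublets kept and 16.2-fold with separate clustering. The creatine kinase gene Ckb (34.4-fold, 24.2 to 50.5), Fam189b (31.5-fold, 21.95 to 46.9, or 18.3-fold with doublets kept), Sytl2 (25.3-fold, 18.4 to 35.99), Ypel3 (21.4-fold, 17.1 to 27.1), 2900026A02Rik (21.3-fold, 13.9 to 34.2), Prrt1 (21.1-fold, 14.3 to 32.5) and Btbd11 (19.2-fold, 12.3 to 31.8) were lower too. Sytl2 and Prrt1 were also among the lowest in T cell-like cells. MHC class II genes were lower in 4 of 10 and higher in 1 (median -0.83), at the 20.3 percentile of random lists, so the list was not set apart from similar genes. The 4 lower were under 10% of the level in the highest class, and the leading Ciita, H2-DMa and H2-Oa stood at 3.41-, 2.27- and 2.52-fold lower with doublets kept. The gelatinase gene Mmp9 was 28.6-fold lower (18.9 to 45.3) and was also under 10% of the level in the highest class. Of the cell cycle list, 7 of 14 were lower and 0 higher (median -0.96), 6 of them under 10% of the level in the highest class, with 2 lower under TMM scaling, 2 at a minimum of 100 UMIs and 4 with separate clustering. The LPS and dsRNA sensing list stood at 5 of 14 higher and 0 lower (median 0.09, or -0.34 in the lowest pair of clusters).

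B cell-like cells of the LPS library had higher type I interferon response, MHC class I and activation genes, and several MHC class II genes were lower. All 29 measured type I interferon response genes were at least 2-fold higher (median 5.55, 100 percentile), 2 of them under 10% of the level in the highest class. Of the MHC class I list, 11 of 16 were higher and 0 lower (median 1.36), whereas of the MHC class II list 4 of 11 were lower and 1 higher (median -0.84, 0.01 percentile). Nearly all of these cells lay in cluster 10 in the control and cluster 6 in the LPS library.

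Isg15, the ubiquitin-like interferon-stimulated gene, stood at 7.84 CPM in the control and 881 CPM in the LPS library, 112-fold higher (70.03 to 193). Ifit1 (139.9-fold, 70.8 to 325), Ifit2 (125-fold, 74.1 to 228), Ifit3 (145-fold, 94.98 to 235), Mx1 (137-fold, 76.1 to 274), Oas3 (134-fold, 65.1 to 335), Usp18 (152-fold, 69.8 to 416) and Slfn5 (109-fold, 82.99 to 146) were higher as well. For the other named genes the control held only 1 to 4 UMIs, and the count added moves the ratio: Ifit3b (236-fold, 80.6 to 1148, or 119-fold with 3 added to each count), Oas2 (187-fold, 72.7 to 687, or 107-fold), Trim30c (143-fold, 39.2 to 1181, or 57.5-fold) and Gm47242 (195-fold, 34.7 to 7740.02, or 49.4-fold), a gene model that overlaps another gene. Interferon-gamma targets were higher in 16 of 18 genes and lower in 1 (median 3.85, or 3.33 with genes at 0 set at their bound), with Cxcl10 at 9.22 against 869.8 CPM, 94.3-fold higher, 60.9 to 155 (147-fold with doublets kept, and under 10% of the level in neutrophil-like cells), and Tgtp2 at 0 in the control and 36.6 CPM in the LPS library, at least 26.5-fold higher. Of the 16 higher interferon-gamma targets, 3 were under 10% of the level in the highest class. Nlrc5, the transactivator of MHC class I genes, was 10.2-fold higher (7.93 to 13.2), with Psme1 (4.71-fold, 4.28 to 5.198) and Tap1 (4.32-fold, 3.802 to 4.92).

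Among MHC class II genes of B cell-like cells, Ciita, the class II transactivator, stood at 273 CPM in the control and 109.9 CPM in the LPS library, 2.48-fold lower (2.16 to 2.85), and the peptide exchange genes H2-DMa (2.43-fold, 2.19 to 2.69) and H2-DMb1 (2.596-fold, 2.17 to 3.11) were also lower. Cd86 was 2.61-fold (2.19 to 3.12) and Cd40 4.34-fold (3.53 to 5.37) higher. Among lymphocyte activation genes (7 of 14 higher, 1 lower, median 1.02), Myc was 8.19-fold (7.08 to 9.53) and Cd69 4.499-fold (4.12 to 4.92) higher. The macrophage growth factor gene Csf1 had 3 UMIs in the control and 315 in the LPS library (77.9-fold, 26.4 to 379.98, or 39.3-fold with 3 added to each count). The cytokine list had 4 of 9 genes higher and 0 lower (median 0.81), or 8 higher with doublets kept and 2 over genes with at least 100 UMIs. The 4 higher of 7 chemokine genes (Cxcl10, Ccl2, Ccl4 and Ccl3) were each under 10% of the level in the highest class of the LPS library, with Ccl4 at 182 CPM in B cell-like and 5872 CPM in NK/ILC1-like cells and at 2.27-fold, or 4.01-fold with doublets kept, and are not read as B cell expression. The NF-kB feedback and targets list had 5 of 21 higher and 2 lower (median 0.33), with Socs3 7.301-fold higher (5.84 to 9.24). Zbp1 (43.3-fold, 31.6 to 61.1) and Casp4 (18.3-fold, 13.1 to 26.5) were among the higher genes of the inflammasome and lytic death list (7 of 15 higher, 1 lower, median 0.45). Mlkl had the largest log2 ratio of that list (6.17, or 3.66 with 3 added to each count). It was at 0 in the control and at least 11.9-fold higher. The LPS and dsRNA sensing list had 4 of 15 genes higher and 2 lower (median 0.25, or -0.04 with doublets kept).

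Lower in B cell-like cells of the LPS library were the B cell marker genes Fcer2a (CD23), at 399 CPM in the control and 46.2 CPM in the LPS library, 8.64-fold lower (7.201 to 10.4), and Cd79b (2.15-fold, 2.03 to 2.28), and the complement decay gene Cd55 (4.602-fold, 4.05 to 5.24). By the naming rule the lowest were Rassf3 (22.4-fold, 13.5 to 39.8), the ubiquitin ligase gene Trim7 (13.6-fold, 9.79 to 19.3), the cell cycle phosphatase gene Cdc25b (13.6-fold, 8.38 to 23.5), Mical1 (13.5-fold, 7.77 to 25.3), Grap2 (10.1-fold, 7.097 to 14.8, or 5.45-fold with doublets kept), Tbc1d10c (9.98-fold, 7.44 to 13.7), the cofilin phosphatase gene Ssh1 (8.98-fold, 5.65 to 14.96) and the adenylate cyclase gene Adcy7 (8.76-fold, 6.45 to 12.1). Cybb, a subunit of the phagocyte NADPH oxidase, was 7.97-fold higher (7.22 to 8.81) and the retention receptor gene Cxcr4 2.78-fold lower (2.52 to 3.06). The cytotoxic effectors list was higher in 5 of 11 genes with a median of 0.81, of which 4 were under 10% of the level in the highest class, and its leading gene Gzmb, at 263 CPM in B cell-like cells of the LPS library against 12448 CPM in NK/ILC1-like cells, moved from 7.59-fold to 31.2-fold higher with doublets kept.

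**Figure D2:**
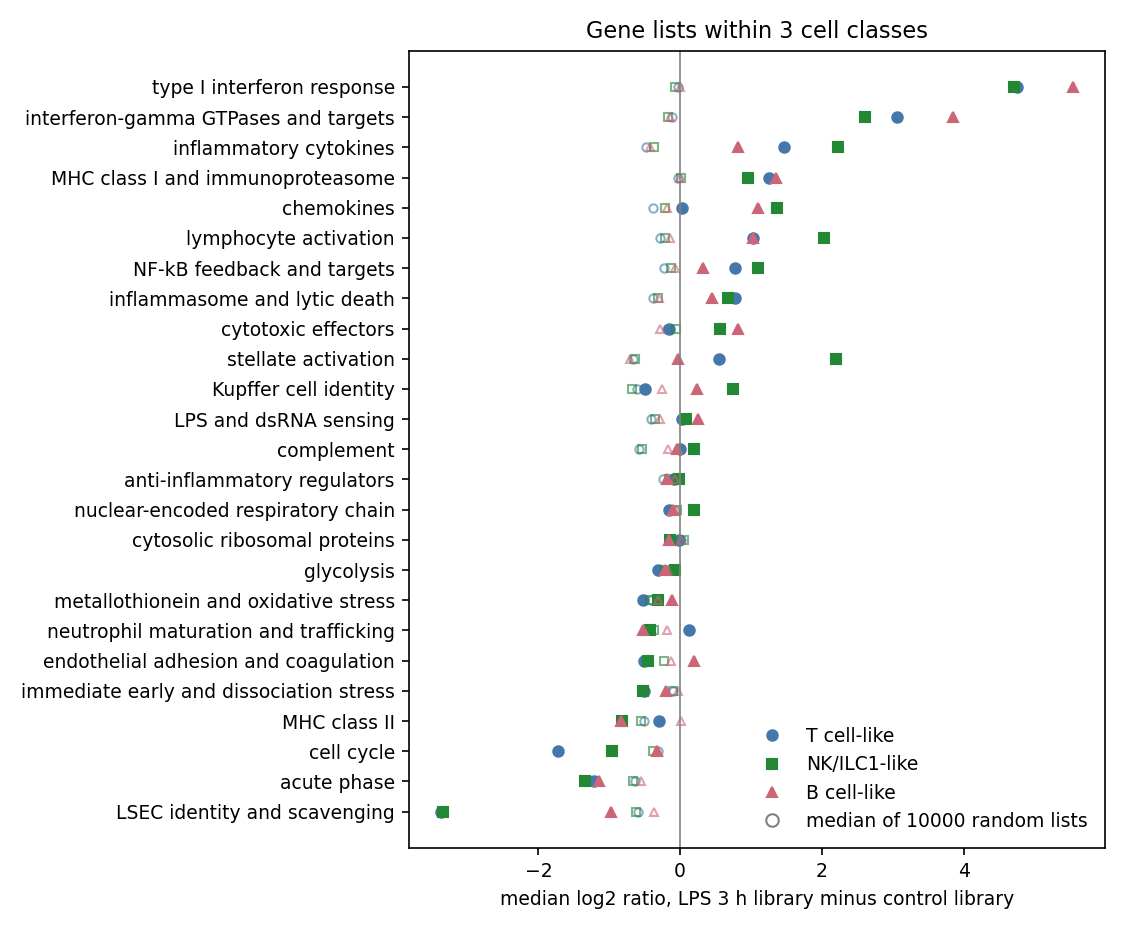
Median log2 ratio (LPS over control, CPM) of each gene list in T cell-like, NK/ILC1-like and B cell-like cells as filled symbols, with the median of random lists of equal size and similar expression as open symbols, 1 library per group. The type I interferon response list stands at 4.75, 4.71 and 5.55, and the MHC class II list at -0.29 (0.08 under TMM scaling), -0.83 and -0.84.

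Of the lists of other liver cells, read in lymphocytes, the LSEC identity and acute phase lists had negative medians in each of the 3 classes, and the Kupffer and stellate lists went both ways. In the order T cell-like, NK/ILC1-like and B cell-like cells, used for the lists from here on, LSEC identity genes had median log2 ratios of -3.37, -3.35 and -0.98, with 13 of 17, 8 of 10 and 2 of 4 genes lower (4, 1 and 0 over genes with at least 100 UMIs), and the first of these medians was -2.60 and the second -2.88 with genes at 0 set at their bound. LSEC markers summed to 37.9, 41.6 and 131 CPM in the control and 14.1, 24.9 and 62.98 CPM in the LPS library. Acute phase genes had medians of -1.22, -1.34 and -1.15, with 11 of 17, 7 of 11 and 6 of 10 lower, and the last median turned to 2.06 over genes with at least 100 UMIs. Those lower were 6 in T cell-like and 3 in B cell-like cells under TMM scaling, 3 in NK/ILC1-like cells with doublets kept, and 7, 4 and 0 over genes with at least 100 UMIs. Hepatocyte markers summed to 111, 119.9 and 138 CPM in the control and 58.1, 42.6 and 64.4 CPM in the LPS library. Saa3, a member that myeloid cells express, was 4.42-fold higher in T cell-like cells (3.73 to 5.25), where the monocyte-like cells of the same library held 20513 CPM.

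Kupffer cell identity genes had medians of -0.50, 0.75 and 0.23 over 7, 4 and 2 measured genes, at the 60.96, 98.2 and 72.3 percentile of random lists, and each changed sign with another minimum of UMIs. Il18bp, the soluble inhibitor of interleukin-18, was 8.36-fold higher in T cell-like cells (6.71 to 10.5), where it was under 10% of the level in the highest class. The endothelial adhesion and coagulation list had medians of -0.50, -0.45 and 0.20, the last turning to -0.13 with doublets kept. The stellate activation list had medians of 0.55, 2.21 and -0.03 over 6, 2 and 1 genes, at the 98.8, 99.1 and 73.1 percentile, the second turning to -0.08 with doublets kept and the last to 0.28 under TMM scaling, and its leading gene in NK/ILC1-like cells was Spp1 (osteopontin), 28.6-fold higher (13.6 to 72.3), or 11.5-fold with doublets kept and 16.5-fold with the stricter filter. Complement genes had medians of -0.01, 0.19 and -0.04, the first turning to 0.36 and the last to 0.27 under TMM scaling. The neutrophil maturation and trafficking list had medians of 0.13, -0.42 and -0.52, the first turning to -0.51 without a UMI minimum and to -0.13 under the first naming rule. In T cell-like cells its member Mmp9 was 9.87-fold lower (8.68 to 11.3), or 25.6-fold under the first naming rule. Mmp9 was under 10% of the level in the highest class there.

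Metabolic, stress and housekeeping lists had small medians. Glycolysis genes had medians of -0.31, -0.08 and -0.22, all of which became positive under TMM scaling (0.06, 0.26 and 0.09), while the hexokinase gene Hk2 was 13.2-fold higher in B cell-like cells (7.56 to 25.1). The metallothionein and oxidative stress list had medians of -0.53, -0.31 and -0.11, the last pair turning to 0.03 and 0.20 under TMM scaling, with the catalase gene Cat 9.48-fold lower in B cell-like cells (6.36 to 14.6). Cat was under 10% of the level in the highest class there. Immediate early and dissociation stress genes had medians of -0.51, -0.53 and -0.21, at the 1.605, 1.75 and 15.4 percentile of random lists, the last median turning to 0.11 under TMM scaling. In T cell-like cells Nr4a1 was 2.68-fold lower (2.52 to 2.86) and Atf3 3.95-fold higher (3.39 to 4.61), with Atf3 under 10% of the level in the highest class. Anti-inflammatory regulators had medians of -0.08, -0.02 and -0.18, or 0.29, 0.32 and 0.13 under TMM scaling. Cytosolic ribosomal proteins had medians of -0.02, -0.14 and -0.15, or 0.35, 0.20 and 0.16 under TMM scaling, and 0 of 25 measured genes were 2-fold apart in any of the 3 classes. Respiratory chain genes had medians of -0.16, 0.20 and -0.10, the first turning to 0.21 and the last to 0.21 under TMM scaling. The cell cycle list in B cell-like cells had a median of -0.33, or 0.08 without a UMI minimum. MHC class II genes in T cell-like cells had a median of -0.29, or 0.08 under TMM scaling.

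Which classes held the cytokine genes was addressed by the share of a gene's UMIs in each class, and the leading class differed between the libraries for some genes and was the same for others. Ifng UMIs lay mostly in T cell-like cells in the control (71.4%, 70.5 to 72.3%) and mostly in NK/ILC1-like cells in the LPS library (62.5%, 61.7 to 63.3%). Per cell class, Ifng stood at 166 and 184 CPM in T cell-like cells and at 251 and 1170.3 CPM in NK/ILC1-like cells. For Ccl5 and Xcl1 the leading class changed likewise, from T cell-like cells in the control (52.6% and 55.7%) to NK/ILC1-like cells in the LPS library (57.8% and 66.4%). T cell-like cells held 69.8% and 66.1% of all UMIs in the control and LPS libraries, and NK/ILC1-like cells 15.7% and 17.7%. The Ccl5 level was higher in NK/ILC1-like cells in both libraries, at 12913 and 13958 CPM. In T cell-like cells Ccl5 stood at 3492 and 2352 CPM. Xcl1, whose product attracts cross-presenting dendritic cells, stood at 1339 and 2567 CPM in NK/ILC1-like cells and at 416 and 341 CPM in T cell-like cells. Ccl3 and Ccl4 were mostly held by NK/ILC1-like cells in both libraries (61.1% and 77.5%, 61.6% and 74.5%).

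Cxcl10 UMIs numbered 2338 in the control and 161692 in the LPS library, of which T cell-like cells held 69.1% and 63.9%. Its CPM level in the LPS library was highest in neutrophil-like (19843 CPM) and monocyte-like cells (14865 CPM). Neutrophil-like cells held most Il1b UMIs (88.98% and 59.1%) and most Cxcl2 UMIs in the control (79.3%, against 49.8% in the LPS library). Il6 UMIs lay largely in cluster 25 in the control (71.4% of 35 UMIs) and in the LPS library (50% of 172 UMIs). Monocyte-like cells of the LPS library held 61.8% of Il27, 60.8% of Ccl7 and 89.9% of Ccl12 UMIs. Hepatocyte-like barcodes held 92.6% of the Cxcl1 and 99.6% of the Cxcl12 UMIs of that library. T cell-like cells held 74.8% and 79.7% of Tnf UMIs, beside 69.8% and 66.1% of all UMIs, at 29.6 and 37.7 CPM. Tnf stood at 31.9 and 17.8 CPM in NK/ILC1-like cells, and its level in the LPS library was highest in neutrophil-like cells (263 CPM). Il12b, found in 191 UMIs of the control, was held by monocyte-like cells (95.8%).

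**Figure D3:**
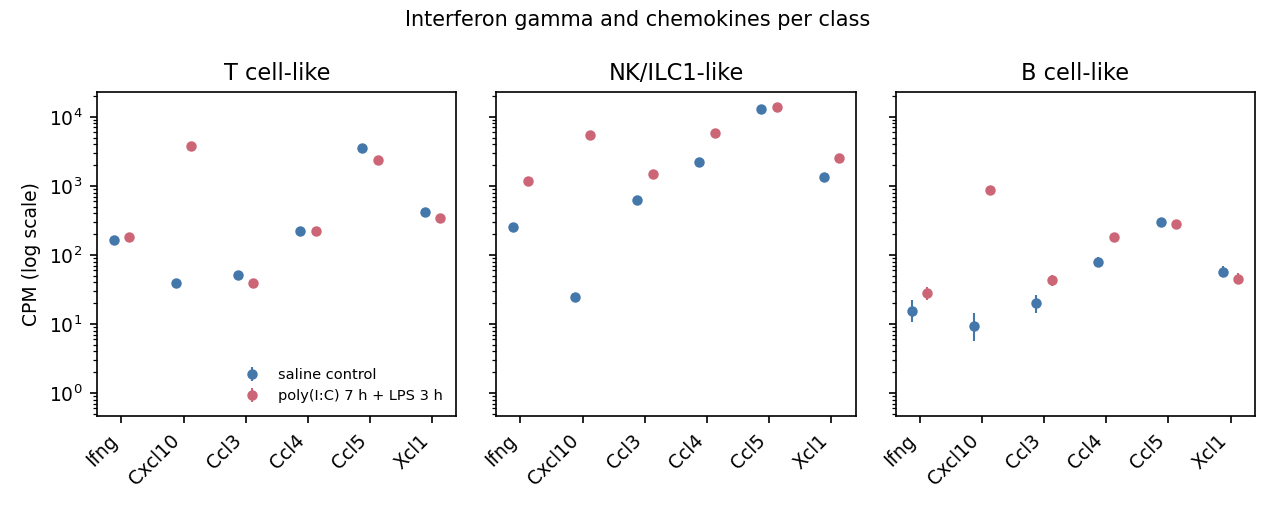
Level of Ifng and 5 chemokine genes (CPM, log axis) in T cell-like, NK/ILC1-like and B cell-like cells of the control and LPS libraries, with exact 95% Poisson intervals as error bars, 1 library per group. Ifng stands at 251 and 1170.3 CPM in NK/ILC1-like cells and at 166 and 184 CPM in T cell-like cells.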

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

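In this part, the tests of free RNA and of fragments for the hepatocyte-like barcodes and the tests of lost marker transcripts and of barcode filtering and doublet removal for the LSEC-like cells were chosen only after the result was seen.

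The library of mice 12 h after LPS lists 49844 barcodes, against 12084 in the control and 14542 in the 3 h library. What drew attention is a number of barcodes far above the control in a library whose expression was not used in any comparison. Whether its barcode list holds called cells is not given in the sources used here, so the numbers are not on equal terms. No explanation was tested.

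Hepatocyte-like barcodes were 0.199% of the control and 27.3% of the LPS library. Droplets that hold free RNA of 1 shared pool are argued against: the ratio of pericentral to periportal UMIs was 23.2 times higher (21.0 to 25.6) in the 590 barcodes with a Cyp2e1 UMI than in the 2825 without. Damaged hepatocytes or fragments stay open: under the stricter filter 2.03% of the LPS share was left, but the low depth of these barcodes, seen beforehand, fixes that outcome. A separation of hepatocytes that differed between the preparations cannot be told apart from the treatment, with 1 preparation per group. An effect of the treatment on hepatocytes stays open and untested.

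Type I interferon response genes were higher in T cell-like, NK/ILC1-like and B cell-like cells of the LPS library. Free RNA is argued against, since each class held at least 2.44 times the list's UMIs per barcode of erythroid-like barcodes, 55.4 (B cell-like) to 105.5 (T cell-like) against 22.7, at median depths of 2450 and 4097.5 against 4149 UMIs. Different clusters in each library are argued against by the lowest median log2 ratio over all pairs of clusters, 3.46, and scaling by the lowest median under TMM or the reduced total, 4.66. A response of the lymphocytes to poly(I:C) and LPS is therefore a candidate explanation, as a hypothesis found and tested on the same libraries, with the agents not separated.

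LSEC-like cells were 2.44% of the control and 0.0160% of the LPS library. Among kept barcodes, cells present without their marker transcripts are argued against. Summed over these barcodes, 10 endothelial genes outside the lists had a median log2 ratio of -6.09 (lowest gene -8.82, highest gene -4.87), with Egfl7 at 2152 and 46 UMIs. Barcodes called as doublets were not in these sums and are not covered. Removal by the barcode filter alone or with doublets alone is argued against as well, since the share reached at most 8.94% of the control share with either step left out. The steps were not left out together. The matrices hold no barcode under 500 UMIs, so a loss below that depth is not covered. A lower yield of endothelial cells from the digested liver cannot be told apart from a loss of these cells in the animals, with 1 preparation per group.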

How the results depend on the processing

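Chosen only after the result was seen were the shares without hepatocyte-like barcodes, the pairs of clusters, the T cell-like cells without cluster 17, the naming rule first written and the NK/ILC1-like genes between clusters with and without Eomes. No paired analysis was possible because each group has 1 library and the results come from no test. Over all alternatives, 48 of 78 class shares stayed within their intervals and 30 moved, 2475 of 2968 gene ratios stayed, 479 moved and 14 reversed, 1141 of 1352 list counts stayed and 211 moved, 669 of 774 list medians stayed, 99 moved and 6 reversed, and 57 of 124 cytokine shares stayed and 67 moved. The cause was not tested for any of them unless stated. The intervals are narrow because they hold counting error only.

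Of the class shares, the stricter filter gave, in the control and LPS libraries, 74.1% and 65.2% T cell-like, 12.6% and 20.3% NK/ILC1-like and 0.0999% and 0.553% hepatocyte-like barcodes, and 12.1% B cell-like cells in the LPS library, where removing hepatocyte-like barcodes shrinks the denominator. Without a filter the shares were 65.4% and 45.9% for T cell-like, 14.4% for NK/ILC1-like cells of the control and 28.2% for hepatocyte-like barcodes of the LPS library. With doublets kept they were 65.8% for T cell-like cells of the control, 6.47% and 9.51% for B cell-like, 24.5% for hepatocyte-like barcodes of the LPS library, and 2.93% and 0.262% for LSEC-like cells. Clustering each library on its own gave 70.6% and 44.9% T cell-like, 16.7% NK/ILC1-like and 0% LSEC-like cells, the last pair in the LPS library. Keeping response genes gave 69.8% and 45.4% T cell-like and 16.9% NK/ILC1-like cells of the LPS library, and resolution 2 gave 70.0% T cell-like cells of the control. Without hepatocyte-like barcodes, the LPS library held 65.3% T cell-like, 20.2% NK/ILC1-like and 12.1% B cell-like cells. The first naming rule, which leaves clusters 1, 3 and 28 out of the class, gave 26.7% and 26.3% T cell-like cells.

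A gene ratio counted as reversed when its main interval excluded 1 and its sign changed, and a list median when it was at least 1 in size and its sign changed. TMM scaling gave 0.13 for Rpl3 and 0.0487 for Sdha in T cell-like, 0.00533 for Rpl23 in NK/ILC1-like, and 0.0613 for Rplp1, 0.0527 for Rps3 and 0.0471 for Rpl8 in B cell-like cells, where 1 factor per class shifts every gene. In NK/ILC1-like cells, Ncr1 turned to -0.13 under the stricter filter and Klra4 to -0.38 with the mean of each cell's CPM, -0.46 under the stricter filter and -0.0342 with separate clustering. In B cell-like cells with doublets kept, Klf2 turned to -0.13 and Txnrd1 to 0.0675. Under the first naming rule Il7r turned to -0.11 in T cell-like cells, and Eomes to -0.21 between clusters 14 and 5 of NK/ILC1-like cells. Ratios whose interval held 1 changed sign as well, among them Mki67 in B cell-like (from 0.55 to -0.86 with the mean of each cell's CPM), Serping1 in NK/ILC1-like (from 0.31 to -0.53 under the stricter filter) and Col3a1 in T cell-like cells (from -0.86 to 0.195 under the first naming rule).

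Counts of list members moved for 50 of 150 counts at a minimum of 1 UMI and 34 at 100 UMIs, which changes how many genes are measured, and for 42 under TMM scaling. In T cell-like cells, members at least 2-fold higher went from 9 to 5 for inflammatory cytokines and from 5 to 1 for the endothelial list at a minimum of 100 UMIs, and from 6 to 10 for chemokines and from 5 to 8 for the endothelial list at 1 UMI. Members at least 2-fold lower went from 8 to 0 (endothelial), from 13 to 4 (LSEC identity), from 11 to 7 (acute phase) and from 5 to 3 (neutrophil) at 100 UMIs. TMM scaling gave 5 endothelial, 6 acute phase and 2 neutrophil genes lower and 9 inflammasome genes higher instead of 5, doublets kept gave 3 neutrophil genes lower, and cell cycle genes lower went from 12 to 5 without cluster 17. The first naming rule gave 5 inflammatory cytokines higher and 3 endothelial genes higher and 4 lower.

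In NK/ILC1-like cells, members higher went from 8 to 5 for inflammatory cytokines at 100 UMIs, and from 6 to 11 for chemokines and 5 to 8 for LPS and dsRNA sensing at 1 UMI. Members lower in the LSEC identity list went from 8 to 17 at 1 UMI, 1 at 100 UMIs and 5 under the stricter filter. Acute phase genes lower went from 7 to 4 at 100 UMIs and 3 with doublets kept, and cell cycle genes lower from 7 to 2 at 100 UMIs, 2 under TMM scaling and 4 with separate clustering. In B cell-like cells, NF-kB genes higher went from 5 to 8 under TMM scaling, cytotoxic genes higher from 5 to 3 at 100 UMIs and 11 with doublets kept, and acute phase genes lower from 6 to 12 at 1 UMI, 0 at 100 UMIs and 3 under TMM scaling. List medians that reversed were stellate activation in NK/ILC1-like cells (-0.0812 with doublets kept, -0.46 in the lowest pair of clusters, over 2 genes), acute phase in B cell-like cells (2.06 at 100 UMIs) and, in the highest pair of T cell-like clusters, LSEC identity (1.11), acute phase (0.83) and cell cycle (5.44). Smaller medians changed sign more often: over the pairs of clusters, medians of both signs occurred for 18 of 25 lists in T cell-like and 9 of 25 in NK/ILC1-like cells, such as endothelial adhesion (2.09) in T cell-like cells. Kupffer identity turned to -1.93 in NK/ILC1-like cells at 100 UMIs.

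Cytokine shares moved as follows, and the leading class was kept in each case given here. With doublets kept and with separate clustering, Ifng stood at 67.5% and 73.4% in T cell-like cells of the control and 59.0% and 64.8% in NK/ILC1-like cells of the LPS library. Cxcl10 stood at 62.0% in T cell-like cells of the control with doublets kept, and at 59.5% and 57.3% in those of the LPS library. In NK/ILC1-like cells Ccl3 stood at 58.7% and 57.1% in the control and 72.2% and 79.9% in the LPS library, and Ccl4 at 58.0% and 57.5% and at 71.0% and 77.7%. Ccl5 stood at 50.2% and 56.0% in T cell-like cells of the control and 54.1% and 63.9% in NK/ILC1-like cells of the LPS library, and Xcl1 at 53.3% and 58.7% and at 63.9% and 75.3%.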

Other observations

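No new test is reported in this part, and its items were chosen after the values were seen. Monocyte-like and neutrophil-like cells of the LPS library held more UMIs of the interferon list per barcode than its T cell-like, NK/ILC1-like and B cell-like cells. The type I interferon list held 22.8 UMIs per barcode in monocyte-like cells of the control and 282 in those of the LPS library, and 8.47 and 145 in neutrophil-like cells. Monocyte-like cells of the LPS library were led by Saa3, Chil3, Il1rn and Slfn4, and held 42.6% of the Il18 and 52.3% of the Ccl9 UMIs of that library. Those of the control held 95.8% of the Il12b, 85.6% of the Ccl22 and 68.6% of the Ccl17 UMIs, which are genes of activated dendritic cells, so the cells under this name in the 2 libraries are not shown to be of 1 cell type and their interferon values are no change within a type.

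The hepatocyte-like barcodes of the LPS library held 0.348 UMIs of the interferon list per barcode (0.328 to 0.368) at a median of 696 UMIs, and the 21 of the control 2.95 (2.26 to 3.78) at a median of 834 UMIs. These are means per barcode, not scaled to depth, and the medians hide a higher mean depth in the control. There, 10 Cxcl12 UMIs in the 21 barcodes stood at only 115 CPM. The interferon values are therefore not read as a change in level. The hepatocyte-like barcodes of the LPS library held 932 Cxcl1 UMIs (367 CPM) and 785 Cxcl12 UMIs (309.5 CPM). The 2 LSEC-like cells of the LPS library held 187 Ccl2 UMIs, 23.001% of that gene's total in the library, and 21 Cxcl1 UMIs.

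Markers of Kupffer cells, the resident macrophages of the liver, were nearly missing from both libraries. Over all barcodes of the control and LPS libraries, Clec4f had 3 and 1 UMIs, Vsig4 0 and 0, Timd4 2 and 0, Cd5l 2 and 4, and C1qb 54 and 165. Slc40a1, which other cells express as well, had 475 and 674 UMIs.

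Hepatocyte, LSEC and erythroid markers, summed as a measure of free RNA in lymphocytes, were each lower in the LPS library. Such sums do not separate free RNA from transcripts of the lymphocytes themselves, and no myeloid source was summed. Saa3, highest in monocyte-like cells of the LPS library, was at least 2-fold higher in all 3 lymphocyte classes. Erythroid markers summed to 824 and 154 CPM in T cell-like, 842 and 218 CPM in NK/ILC1-like and 952 and 182 CPM in B cell-like cells of the control and LPS libraries. A set of T cell-like cells led by Il22, Il17a and Il17f (cluster 28) numbered 59 in the LPS library and 0 in the control, where cluster 13 with 551 cells was led by Cd8b1 and Il17a.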
